A study of Mus musculus with 12 samples.

How the data were processed

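Gene expression was measured by RNA sequencing in macrophages sorted from mouse mammary ducts, with 3 libraries at each of 4 stages. Per the labels' protocols, RNA was isolated from freshly sorted cells, cDNA was made with the SMART-Seq v4 Ultra Low Input kit, a full-length method for small samples, and all libraries were barcoded and sequenced in 1 run. The kit adds no molecular identifiers, so PCR copies of a molecule are counted as separate reads. The authors deposited raw read counts per gene, whole numbers that are not normalized, and per the submitters' processing notes these came from featureCounts with the mm10 mouse genome. The aligner, its settings, the version of featureCounts and its strand setting are not given in the sources used here. Reads from overlapping or antisense genes therefore cannot be told apart. Genes with near-identical copies or pseudogenes are uncertain too, among them ribosomal protein genes, MHC class I genes and Lilr4b, which has a close paralog. How the cells were gated is not given in the sources used here.

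Each of the 12 tables held 27179 genes under Entrez identifiers, and a table of the whole series held the same counts in every cell. Symbols and coordinates were taken from a RefSeq gene table of GRCm38.p6, the assembly behind mm10, which matched 25275 genes (93%), and the rest held at most 0.82% of the counts of a library. Coordinates are 1-based. Library totals ran from 6926273 to 21204704 counts. No pair of libraries of a stage was identical, and each pair differed by more than sampling noise. Samples were grouped by the stage in their labels.

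Tests, gene lists, the rule for naming genes and the alternatives were fixed before the data were examined, except where the text says otherwise. Low-count genes were removed with filterByExpr by stage, which left 12672 genes. Libraries were scaled by TMM, and edgeR 4.0.16 (R 4.3.3) fitted 1 robust quasi-likelihood model with a mean per stage to all 12 libraries, so that every comparison shared an estimate of the spread. The common biological coefficient of variation was 0.856. Benjamini-Hochberg adjusted p-values under 0.05 were called changed in each of the 6 pairwise comparisons and in a test of any difference between stages, and adjusted p-values in the text come from this edgeR test unless another tool is named. CPM were computed here from TMM-scaled library sizes. A gene with 0 counts throughout a stage is given a bound in pooled counts, at least N-fold, against a stage floor of 3 counts. Deep libraries weigh more there than in mean CPM.

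Genes named in the text were, per comparison, the 8 largest rises and 8 largest falls among called genes with an official symbol, a mean log2 CPM of at least 3 and no overlap between the stages, the 3 called members with the smallest adjusted p of each list with at least 3 called members, and 10 fixed genes followed at every stage whether changed or not. Members named in brackets beside a count of 5 or fewer, and shared genes of that kind, were chosen after their values were seen. Not every gene that the rule takes is reported here. Of 36 gene lists for pathways, macrophage states and other cell types of the gland, the 33 with at least 5 tested members were tested with camera in limma 3.58.1 at a preset correlation between genes of 0.01, and again with the correlation estimated from the data. The estimated correlation kept 3, 0, 0, 0, 0 and 6 of the 13, 8, 9, 12, 7 and 14 list calls in the order of the comparisons in the text. The share of each library's counts in each list was compared with an exact two-sided permutation test.

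The alternatives were DESeq2 1.42.0, limma-voom with and without quality weights, RLE size factors, TMM computed without milk, epithelial, ribosomal and mitochondrial genes, no low-count filter, a filter of 5 CPM in 3 libraries, a replicate block, a test against a 2-fold change, a fit to the 6 libraries compared, and leaving out each replicate. A fit without Lactating replicate 3 for the comparisons that do not include lactation was added after seeing the data. The procedure was tested on simulated counts for pregnancy against virgin, with 12127 genes in that step. edgeR recovered 1 of 67 genes changed 2-fold (1.49%), 14 of 63 changed 4-fold (22.2%) and 27 of 62 changed 8-fold (43.5%), with 3 false among 45 calls. DESeq2 made 57 false calls among 127 (44.9%). In a step with 12157 genes, a simulated list of 30 genes changed 2-fold passed camera at adjusted p = 3.86e-06, and adjusted p = 0.0151 with an estimated correlation, and of 50 lists no random one passed.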

Results

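RNA was sequenced from macrophages sorted from the mammary ducts of C57BL/6 mice at 4 stages of the reproductive cycle: virgin, day 16.5 of pregnancy, lactation, and 1 month after weaning. Each stage had 3 libraries labelled as biological replicates, 12 in all. The design sets each stage against the others, which asks how the transcripts of these cells differ between the resting, pregnant, milk-producing and regressed gland. Total gene counts were 8704918, 12198862 and 12709036 in the virgin libraries and 8510895, 8425970 and 21204704 in the pregnant libraries. They were 7304269, 6926273 and 10445732 in the lactating libraries and 10633156, 9677825 and 11576516 in the post-weaning libraries. Levels are given as CPM (counts scaled to a common library size), mean ± SD over n = 3 libraries, and log2 fold changes with their standard error. Gene positions are those of GRCm38.p6. The p-values measure the spread between the samples labelled biological replicates, and counting intervals and lower bounds cover counting error only.

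Macrophage transcripts were abundant at every stage. Cd74, the invariant chain of MHC class II, reached 66182 ± 2919 CPM in virgin, 47735 ± 9161 in pregnant, 90469 ± 51429.6 in lactating and 83505 ± 7759.6 in post-weaning libraries. Adgre1, which encodes F4/80, stood at 744 ± 66.5, 608 ± 112, 715 ± 394 and 742 ± 59 CPM in the same order, and the CSF-1 receptor gene Csf1r at 1051 ± 18.8, 1270.0 ± 117, 1269 ± 675 and 1078 ± 156 CPM. Itgax, which encodes CD11c, ranged from 228 ± 44.2 CPM after weaning to 390.0 ± 103 CPM in lactation, and the integrin gene Itgam stayed low, from 3.95 ± 1.89 CPM in pregnancy to 12.6 ± 3.74 CPM in virgin libraries. None of these 5 genes, nor H2-Ab1 or the proliferation marker Mki67, passed the edgeR test in any of the 6 pairwise comparisons, where their lowest adjusted p was 0.242, for Itgax. Mrc1, the mannose receptor CD206, had 99 ± 30.9 CPM in virgin, 4.68 ± 1.7 in pregnant, 10.4 ± 10.8 in lactating and 159 ± 27.6 in post-weaning libraries, and its lowest edgeR adjusted p was 0.0853.

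The 22 macrophage identity genes took 4 ± 0.299% of the counts in virgin, 6.78 ± 0.211% in pregnant, 3.99 ± 1.67% in lactating and 4.98 ± 0.261% in post-weaning libraries. Milk protein and secretory cell genes took 0.00488 ± 0.00682%, 0.682 ± 0.761%, 2.62 ± 4.23% and 0.117 ± 0.0863%, and luminal epithelial genes 0.0675 ± 0.0722%, 0.0566 ± 0.00744%, 0.0353 ± 0.0193% and 0.0928 ± 0.0485%. Endothelial genes took 0.0116 ± 0.00855% in virgin and 0.00119 ± 0.000821% in pregnant libraries, and the T and NK cell genes at most 0.0024 ± 0.00228%, in lactation. For such shares an exact two-sided permutation test of 3 libraries against 3 cannot give a p under 0.1. Lactating replicate 3 stood apart from the other 11 libraries. Milk genes took 7.5% (exact 95% binomial interval 7.49 to 7.52%) of its counts, against 0.187% and 0.179% in the other lactating libraries, and macrophage identity genes 2.06% (exact 95% binomial interval 2.06 to 2.07%), against 5.11% and 4.78%. It had 10178 genes detected, the fewest of the 12, and Malat1, a nuclear long noncoding RNA, at 40881 CPM of its unscaled total, against 9541 and 13175. Its mean correlation with the other lactating libraries across genes was 0.713, while the libraries of the other stages correlated at 0.793 to 0.917 with their own stage.

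**Figure D1:**
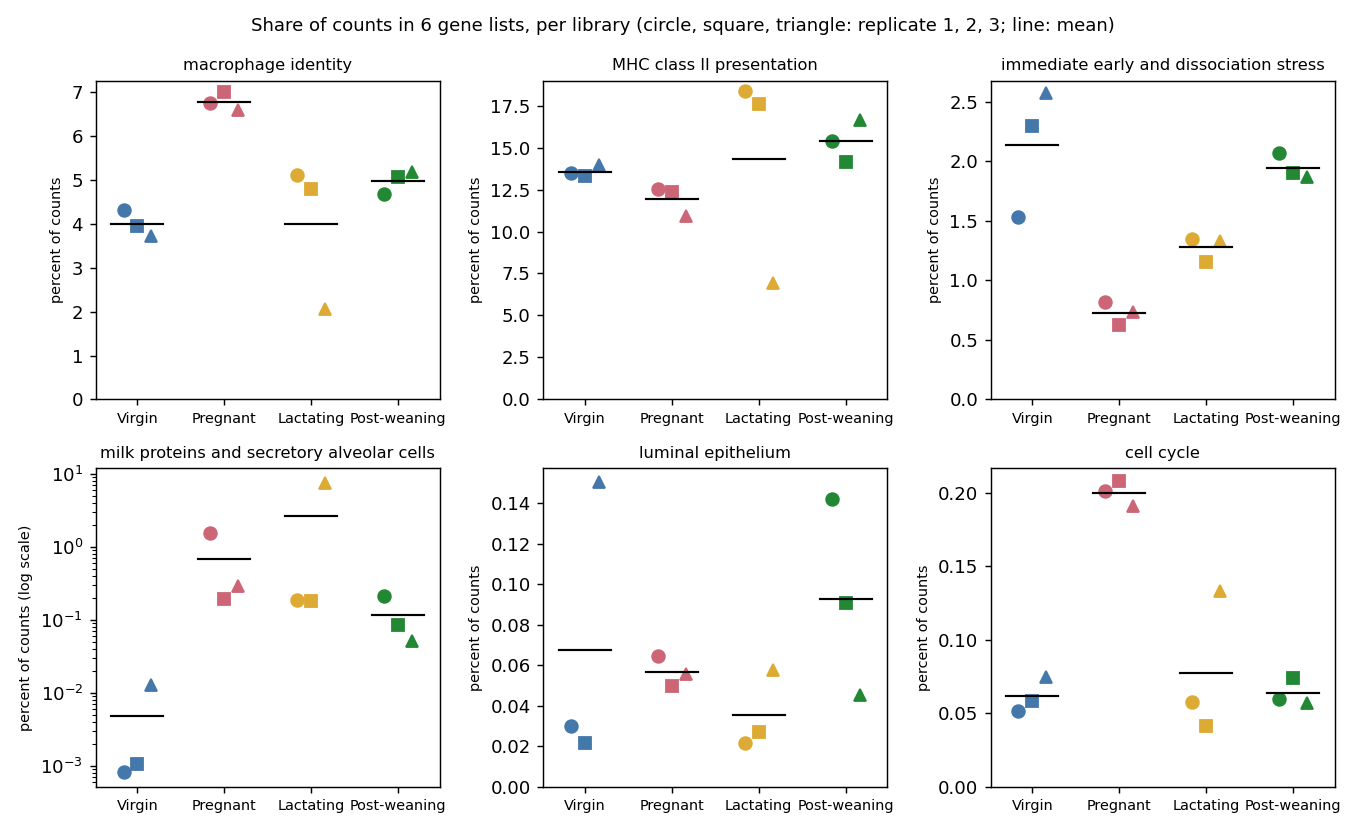
Percent of each library's counts (y axis) taken by 6 gene lists at the 4 stages (x axis), with a circle, square and triangle for replicates 1, 2 and 3, a line for the mean, and a log axis for milk genes only. Lactating replicate 3 lies at 7.5% for milk genes and at 2.06% for macrophage identity, and the pregnant libraries average 6.78 ± 0.211% (SD, n = 3) for macrophage identity.

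**Figure D2:**
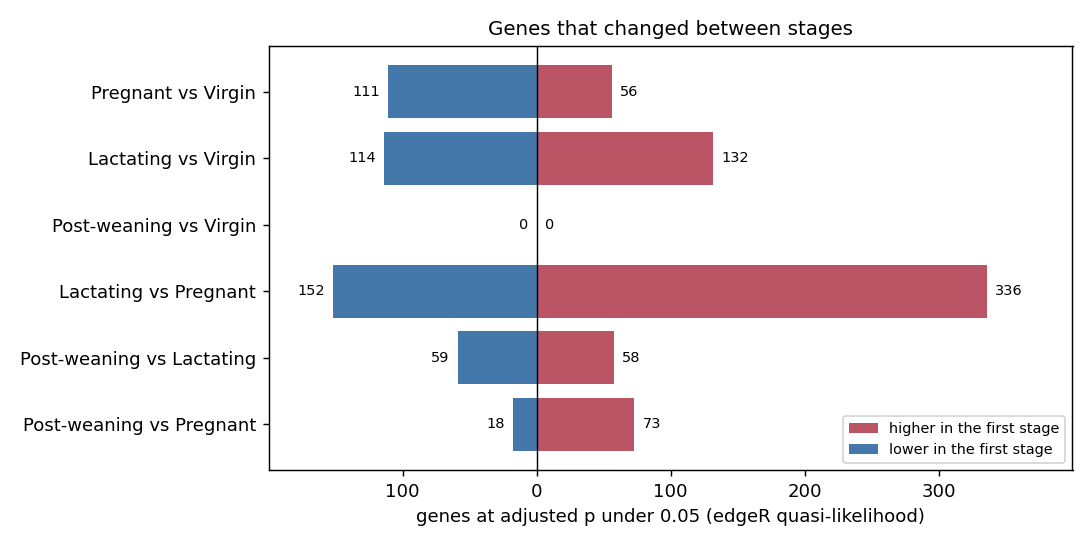
Number of genes (x axis) that passed an adjusted p of 0.05 in edgeR's quasi-likelihood test in each comparison of 2 stages (y axis), to the right where higher and to the left where lower in the stage named first. The bars run from 0 genes after weaning against virgin to 336 higher and 152 lower genes in lactation against pregnancy.

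In pregnant against virgin mice, 12 of the 31 immediate early and dissociation stress genes and 5 of the 31 inflammatory and NF-kB target genes fell, while 2 of the 45 cell cycle genes rose. The inflammatory list lost its camera call, at adjusted p = 0.24 with an estimated correlation, and the other two kept theirs. Lilr4b, an immunoglobulin-like receptor gene of myeloid cells, fell from 1319 ± 417 to 180.1 ± 25.9 CPM (log2 fold change -2.87 ± 0.24, adjusted p = 0.000995, n = 3 per stage). Lilr4b (Entrez gene 14727) lies on chromosome 10, 51480612 to 51486329. Trem2, which encodes a lipid-sensing receptor, fell from 69.9 ± 46.7 to 3.52 ± 2.66 CPM (log2 fold change -4.33 ± 0.66, adjusted p = 0.010). Cd36, a scavenger receptor gene, fell from 853 ± 264 to 152 ± 124 CPM (log2 fold change -2.49 ± 0.49, adjusted p = 0.0318). Lrp1, an endocytic receptor gene, fell from 39.9 ± 13.4 to 6.12 ± 0.598 CPM (log2 fold change -2.70 ± 0.50, adjusted p = 0.0244). Mmp2, a gelatinase gene, rose from 48.9 ± 21 to 242 ± 11.4 CPM (log2 fold change 2.31 ± 0.38, adjusted p = 0.0152). Hmmr, which encodes a hyaluronan receptor that also acts on the mitotic spindle, had 0 counts in virgin and 32.1 ± 2.69 CPM in pregnant libraries, at least 381-fold higher in pooled counts (adjusted p = 0.0201). Colec12, a scavenger receptor gene, had 0 counts in virgin and 15.8 ± 9.93 CPM in pregnant libraries, at least 233-fold higher in pooled counts (adjusted p = 0.00702).

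Of the immediate early and stress genes, 12 of the 31 tested members fell, and 21 did so adjusted over the list alone. Immediate early and stress genes had a median log2 fold change of -1.47, camera adjusted p = 2.95e-25, and adjusted p = 0.0348 with an estimated correlation. Among them, the antiproliferative gene Btg2 fell by 2.12 ± 0.23 on the log2 scale (edgeR adjusted p = 0.00507). The transcription factor gene Klf6 fell by 1.78 ± 0.20 (adjusted p = 0.00507) and the phosphatase regulator gene Ppp1r15a fell by 2.27 ± 0.27 (adjusted p = 0.00668). Of the inflammatory and NF-kB target genes, 5 of the 31 tested members fell (Nfkbia, Nfkbiz, Cxcl2, Nfkbid and Birc3), and 15 did so adjusted over the list alone. Inflammatory and NF-kB target genes had a median log2 fold change of -1.16, camera adjusted p = 2.11e-12, and adjusted p = 0.24 with an estimated correlation. They include Nfkbiz (log2 fold change -1.93 ± 0.27, adjusted p = 0.00761) and Nfkbia (log2 fold change -1.12 ± 0.19, adjusted p = 0.0169), which encode regulators of NF-kB. Of the cell cycle genes, 2 of the 45 tested members rose (Hmmr and Ccnb2), and 6 did so adjusted over the list alone. Cell cycle genes had a median log2 fold change of 2.28, camera adjusted p = 7.19e-15, and adjusted p = 0.0348 with an estimated correlation. Of the oxidative phosphorylation genes, 0 of the 59 tested members passed the test, and 8 rose adjusted over the list alone. Oxidative phosphorylation genes had a median log2 fold change of 0.56, camera adjusted p = 1.44e-12, and adjusted p = 0.0348 with an estimated correlation. Of the glucocorticoid and steroid response genes, 2 of the 18 tested members fell (Errfi1 and Mt1), and 3 did so adjusted over the list alone. Glucocorticoid and steroid response genes had a median log2 fold change of -0.78, camera adjusted p = 0.0243, and adjusted p = 0.182 with an estimated correlation.

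Of the apoptotic cell uptake genes, 3 of the 25 tested members fell (Lrp1, Trem2 and Cd36), and 1 rose and 4 fell adjusted over the list alone. Apoptotic cell uptake genes had a median log2 fold change of -0.35, camera adjusted p = 0.0382, and adjusted p = 0.281 with an estimated correlation. Their mean log2 fold change was 0.07, opposite in sign to their median and their test. Of the lysosomal genes, 1 of the 45 tested members rose (Acp5), and 4 did so adjusted over the list alone. Lysosomal genes had a median log2 fold change of 0.45, camera adjusted p = 0.000159, and adjusted p = 0.547 with an estimated correlation. Of the MHC class I genes, 1 of the 19 tested members rose (H2-Q7), and 2 did so adjusted over the list alone. MHC class I genes had a median log2 fold change of 0.48, camera adjusted p = 0.000375, and adjusted p = 0.24 with an estimated correlation. Of the cholesterol biosynthesis genes, 1 of the 24 tested members rose (Hmgcs1), and 1 did so adjusted over the list alone. Cholesterol biosynthesis genes had a median log2 fold change of 0.73, camera adjusted p = 0.0154, and adjusted p = 0.547 with an estimated correlation. Of the ribosomal protein genes, 0 of the 78 tested members passed the test, with 0 adjusted over the list alone. Ribosomal protein genes had a median log2 fold change of 0.31, camera adjusted p = 0.0154, and adjusted p = 0.734 with an estimated correlation. Many of these have near-identical copies, so their counts are uncertain.

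Lists for other cells of the gland were called as well. Of the milk protein genes, 4 of the 19 tested members rose (Glycam1, Csn1s1, Csn2 and Csn1s2a), and 8 did so adjusted over the list alone. Milk protein genes had a median log2 fold change of 5.93 (5.55 with members absent from 1 stage at their bound), camera adjusted p = 0.00128, and adjusted p = 0.547 with an estimated correlation. Their share of counts was 0.00488 ± 0.00682% in virgin and 0.682 ± 0.761% in pregnant libraries. Csn2, which encodes beta-casein, had 1 count over the virgin libraries and 3111, 316 and 456 CPM in the pregnant libraries (adjusted p = 0.016). Of the endothelial genes, 0 of the 17 tested members passed the test, with 0 adjusted over the list alone. Endothelial genes had a median log2 fold change of -4.22 (-4.00 with members absent from 1 stage at their bound), camera adjusted p = 1.22e-05, and adjusted p = 0.499 with an estimated correlation. Of the fibroblast genes, 1 of the 15 tested members rose (Mmp2), and 1 rose and 4 fell adjusted over the list alone. Fibroblast genes had a median log2 fold change of -4.44, camera adjusted p = 0.00646, and adjusted p = 0.442 with an estimated correlation. The fibroblast share of counts was 0.0616 ± 0.00527% in pregnant and 0.0589 ± 0.0261% in virgin libraries (exact permutation p = 0.8), not lower in pregnancy.

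In edgeR's test 167 of the 12672 genes tested changed, 56 higher and 111 lower, with 1547 at an unadjusted p under 0.05. Over all genes tested, 3071 (24.2%) had no overlap between the 2 stages, where chance gives 10% with 3 libraries against 3, and 167 of them were among those called. The count was 47 without Virgin replicate 2 and 58 without Virgin replicate 3. It was 51, 40 and 54 without Pregnant replicate 1, 2 and 3. Without Lactating replicate 3, a fit chosen after seeing the data, it was 438. 6 of the 29 named genes that were called kept their call whichever replicate was left out: Btg2, Colec12, Klf6, Lilr4b, Nfkbiz and Ppp1r15a. Lost calls numbered 12, 20 and 21 without Virgin replicate 1, 2 and 3, and 19, 21 and 20 without Pregnant replicate 1, 2 and 3. For genes given above that lost theirs, the highest edgeR adjusted p was 0.147 for Cd36, 0.132 for Lrp1, 0.0975 for Hmmr and 0.0975 for Glycam1 without Pregnant replicate 3. It was 0.123 for Birc3, 0.099 for Nfkbia, 0.0648 for Trem2 and 0.0634 for Mmp2 without Pregnant replicate 2. It was 0.106 for Csn2 without Virgin replicate 3. It was 0.0908 for Csn1s1 and 0.0863 for Csn1s2a without Virgin replicate 2. Csn1s1, Csn1s2a and Glycam1 lost their call whichever of the 6 libraries was left out. Lrp1, Hmmr, Birc3, Nfkbia and Mmp2 lost theirs in 5 of these fits, Cd36 in 4, Csn2 in 3 and Trem2 in 1. The uptake list lost its call at adjusted p = 0.0954 without Virgin replicate 2, 0.0527 without Pregnant replicate 2 and 0.195 without Pregnant replicate 3. Ribosomal protein genes lost theirs at adjusted p = 0.167 without Virgin replicate 3, and were lower, at 0.204, without Pregnant replicate 3.

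In lactating against virgin mice, 7 of the 24 cholesterol biosynthesis genes rose, as did the chemokine gene Cxcl3 and the antiviral genes Oasl1 and Rsad2, while Igf1, Cx3cr1 and Gpr34 fell. With an estimated correlation 0 of the 8 lists called by camera kept their call (cholesterol biosynthesis adjusted p = 0.317 with an estimated correlation). Hmgcs1, which encodes an enzyme of the mevalonate pathway, rose from 13.1 ± 5.41 to 115 ± 13.9 CPM (log2 fold change 3.13 ± 0.38, adjusted p = 0.0041, n = 3 per stage). Hmgcs1 (Entrez gene 208715) lies on chromosome 13, 119690351 to 119708260. Fdps, of the same pathway, rose from 5.62 ± 2.79 to 56.9 ± 11.2 CPM (log2 fold change 3.34 ± 0.47, adjusted p = 0.00505). Cxcl3, a neutrophil chemokine gene, rose from 31.6 ± 20.1 to 499 ± 43.7 CPM (log2 fold change 3.98 ± 0.47, adjusted p = 0.0037). Cxcl3 (Entrez gene 330122) lies on chromosome 5, 90786101 to 90788093. Il10, the gene of an anti-inflammatory cytokine, rose from 182 ± 44.9 to 971 ± 416 CPM (log2 fold change 2.41 ± 0.37, adjusted p = 0.00828). Igf1, which encodes insulin-like growth factor 1, had 0 counts in lactating and 8.2 ± 3.33 CPM in virgin libraries, at least 64.9-fold lower in pooled counts (adjusted p = 0.0037). Igf1 (Entrez gene 16000) lies on chromosome 10, 87858265 to 87937047. Cx3cr1, the fractalkine receptor gene of resident macrophages, fell from 384 ± 10.7 to 206 ± 23.3 CPM (log2 fold change -0.90 ± 0.20, adjusted p = 0.0466). Csf1, which encodes the growth factor CSF-1, had 0 counts in virgin and 38.8 ± 31 CPM in lactating libraries, at least 419-fold higher in pooled counts (adjusted p = 0.00492).

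Of the cholesterol biosynthesis genes, 7 of the 24 tested members rose, and 10 did so adjusted over the list alone. Cholesterol biosynthesis genes had a median log2 fold change of 2.50, camera adjusted p = 3.52e-08, and adjusted p = 0.317 with an estimated correlation. Of the inflammatory and NF-kB target genes, 4 of the 31 tested members rose (Il10, Nfkb1, Cxcl3 and Cxcl1), and 14 rose and 1 fell adjusted over the list alone. Inflammatory and NF-kB target genes had a median log2 fold change of 0.83, camera adjusted p = 4.44e-05, and adjusted p = 0.663 with an estimated correlation. The type I interferon list was not called (camera adjusted p = 0.818), and 3 of the 35 tested members rose (Rsad2, Ifi27l2a and Oasl1), and 4 did so adjusted over the list alone. Oasl1 (log2 fold change 3.84 ± 0.47, adjusted p = 0.0041) and Rsad2 (log2 fold change 2.89 ± 0.52, adjusted p = 0.0185), both induced by interferon, were among them. Of the immediate early and stress genes, 3 of the 31 tested members fell (Ier5, Fos and Egr1), and 5 did so adjusted over the list alone. Immediate early and stress genes had a median log2 fold change of -0.38, camera adjusted p = 0.0387, and adjusted p = 0.712 with an estimated correlation. Fos, a subunit gene of the AP-1 transcription factor, fell from 1695 ± 304 to 550.2 ± 63.7 CPM (log2 fold change -1.62 ± 0.22, adjusted p = 0.0041). Ctsd, which encodes the lysosomal protease cathepsin D, fell from 879.8 ± 452 to 227 ± 44 CPM (log2 fold change -1.95 ± 0.38, adjusted p = 0.0256). Gpr34, a microglial receptor gene, fell from 602 ± 294 to 106 ± 55.7 CPM (log2 fold change -2.51 ± 0.54, adjusted p = 0.0382). Of the glycolysis and hypoxia genes, 1 of the 26 tested members rose (Pkm), and 4 did so adjusted over the list alone. Glycolysis and hypoxia genes had a median log2 fold change of 0.53, camera adjusted p = 0.0387, and adjusted p = 0.317 with an estimated correlation. Of the ribosomal protein genes, 0 of the 78 tested members passed the test, with 0 adjusted over the list alone. Ribosomal protein genes had a median log2 fold change of 0.28, camera adjusted p = 0.00255, and adjusted p = 0.826 with an estimated correlation.

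Of the milk protein genes, 7 of the 19 tested members rose, and 14 did so adjusted over the list alone. Milk protein genes had a median log2 fold change of 10.17 (7.84 with members absent from 1 stage at their bound), camera adjusted p = 4.39e-07, and adjusted p = 0.663 with an estimated correlation. Their share was 7.5% in Lactating replicate 3, against 0.187% and 0.179% in the other lactating libraries. Csn2 had 1 count over the virgin libraries and 286, 243 and 14394 CPM in Lactating replicates 1, 2 and 3 (adjusted p = 0.00851). Of the basal and myoepithelial genes, 0 of the 16 tested members passed the test, with 0 adjusted over the list alone. Basal and myoepithelial genes had a median log2 fold change of 1.93 (1.89 with members absent from 1 stage at their bound), camera adjusted p = 0.00741, and adjusted p = 0.663 with an estimated correlation. Their share was 0.0955% in Lactating replicate 3, against 0.0108% and 0.0223%. Of the fibroblast genes, 0 of the 15 tested members passed the test, and 6 fell adjusted over the list alone. Fibroblast genes had a median log2 fold change of -5.47 (-4.53 with members absent from 1 stage at their bound), camera adjusted p = 0.0387, and adjusted p = 0.663 with an estimated correlation. The fibroblast share of counts was 0.0375 ± 0.00775% in lactating and 0.0589 ± 0.0261% in virgin libraries (exact permutation p = 0.4). Krt19, a keratin gene of luminal epithelium, had 0 counts in lactating and 113 ± 116 CPM in virgin libraries, at least 928-fold lower in pooled counts (adjusted p = 0.0041).

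In edgeR's test 246 of the 12672 genes tested changed, 132 higher and 114 lower, with 2129 at an unadjusted p under 0.05. Over all genes tested, 2211 (17.4%) had no overlap between the 2 stages, where chance gives 10%, and 246 of them were among those called. With edgeR fitted to the 6 libraries of these stages alone the count was 0, with 964 at an unadjusted p under 0.05. DESeq2 on all 12 libraries called 1173, 484 higher and 689 lower. The count was 111, 131 and 121 without Virgin replicate 1, 2 and 3, and 416 without Lactating replicate 3. The balance of directions turned to 116 higher and 180 lower without Lactating replicate 1 and 102 higher and 142 lower without Lactating replicate 2. 16 of the 33 named genes that were called kept their call whichever replicate was left out, among them Csf1, Cxcl3, Fdps, Fos, Hmgcs1, Igf1, Il10, Krt19 and Oasl1. Lost calls numbered 11, 15 and 15 without Virgin replicate 1, 2 and 3, and 7, 9 and 4 without Lactating replicate 1, 2 and 3. For genes given above that lost theirs, the highest edgeR adjusted p was 0.17 for Ifi27l2a and 0.161 for Cxcl1 without Virgin replicate 1. It was 0.128 for Ier5, 0.115 for Egr1, 0.114 for Gpr34, 0.0796 for Ctsd and 0.0711 for Rsad2 without Virgin replicate 2. It was 0.119 for Cx3cr1 and 0.0579 for Csn2 without Virgin replicate 3. Cx3cr1 lost its call whichever of the 6 libraries was left out. Ifi27l2a and Cxcl1 lost theirs in 5 of these fits, Ier5 and Egr1 in 4, and Gpr34 and Ctsd in 3. Rsad2 did so in 2 and Csn2 in 1. Immediate early genes lost their list call at adjusted p = 0.238 without Virgin replicate 2, 0.157 without Virgin replicate 3 and 0.103 without Lactating replicate 2. Fibroblast genes lost it at adjusted p = 0.189 without Virgin replicate 2, 0.147 without Lactating replicate 1, 0.0886 without Lactating replicate 2 and 0.0806 without Lactating replicate 3. Glycolysis genes lost it at adjusted p = 0.0848 without Virgin replicate 1, 0.0824 without Lactating replicate 1, 0.0615 without Lactating replicate 2 and 0.0536 without Lactating replicate 3. Basal and ribosomal protein genes lost it at adjusted p = 0.0973 and 0.113 without Lactating replicate 3. Without that replicate endothelial genes, not called with it, were lower at adjusted p = 0.0215.

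After weaning, no single gene passed the test against virgin libraries. Adgre1 had 742 ± 59 CPM after weaning and 744 ± 66.5 CPM in virgin libraries (log2 fold change 0.00 ± 0.37, n = 3 per stage). Cx3cr1 had 419.8 ± 61.3 and 384 ± 10.7 CPM (0.13 ± 0.20), and Mrc1 159 ± 27.6 and 99 ± 30.9 CPM (0.68 ± 0.96). Of the lysosomal genes, 0 of the 45 tested members passed the test, with 0 adjusted over the list alone. Lysosomal genes had a median log2 fold change of 0.30, camera adjusted p = 0.00147, and adjusted p = 0.699 with an estimated correlation. Of the lipid-associated and disease-associated macrophage genes, 0 of the 25 tested members passed the test, and 3 rose adjusted over the list alone. Lipid-associated and disease-associated macrophage genes had a median log2 fold change of 0.32, camera adjusted p = 0.00174, and adjusted p = 0.699 with an estimated correlation. Of the matrix remodelling and growth factor genes, 0 of the 31 tested members passed the test, and 5 rose adjusted over the list alone. Matrix remodelling and growth factor genes had a median log2 fold change of 0.45, camera adjusted p = 0.00818, and adjusted p = 0.582 with an estimated correlation. Of the iron handling genes, 0 of the 20 tested members passed the test, and 1 rose adjusted over the list alone. Iron handling genes had a median log2 fold change of 0.23, camera adjusted p = 0.0313, and adjusted p = 0.582 with an estimated correlation. Of the ribosomal protein genes, 0 of the 78 tested members passed the test, with 0 adjusted over the list alone. Ribosomal protein genes had a median log2 fold change of -0.30, camera adjusted p = 6.83e-05, and adjusted p = 0.699 with an estimated correlation. Of the type I interferon genes, 0 of the 35 tested members passed the test, with 0 adjusted over the list alone. Type I interferon genes had a median log2 fold change of -0.32, camera adjusted p = 0.0413, and adjusted p = 0.699 with an estimated correlation.

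Of the milk protein genes, 0 of the 19 tested members passed the test, and 5 rose adjusted over the list alone. Milk protein genes had a median log2 fold change of 3.31, camera adjusted p = 0.0039, and adjusted p = 0.699 with an estimated correlation. Their share of counts was 0.117 ± 0.0863% after weaning and 0.00488 ± 0.00682% in virgin libraries. Csn2 had 34.9 ± 15.3 CPM after weaning and 1 count over the virgin libraries (edgeR adjusted p = 0.604). Of the luminal epithelial genes, 0 of the 24 tested members passed the test, with 0 adjusted over the list alone. Luminal epithelial genes had a median log2 fold change of 0.75, camera adjusted p = 0.000176, and adjusted p = 0.699 with an estimated correlation. They took 0.142%, 0.0908% and 0.0453% of counts after weaning, and 0.0301%, 0.0218% and 0.151% in virgin libraries. Of the basal and myoepithelial genes, 0 of the 16 tested members passed the test, with 0 adjusted over the list alone. Basal and myoepithelial genes had a median log2 fold change of 0.86, camera adjusted p = 0.0459, and adjusted p = 0.699 with an estimated correlation.

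edgeR called 0 of the 12672 genes, with 765 at an unadjusted p under 0.05. Over all genes tested, 2039 (16.1%) had no overlap between the 2 stages, where chance gives 10%. DESeq2 called 125, limma-voom 11, limma-voom with quality weights 1 and edgeR on the 6 libraries alone 1. Without Lactating replicate 3, a fit chosen after seeing the data, edgeR called 10. The count of lists called was 5 without Virgin replicate 1 and 9 with it. Luminal genes lost their call at adjusted p = 0.0692 without Virgin replicate 1 and 0.11 without Virgin replicate 2. Basal genes lost it at adjusted p = 0.283 without Virgin replicate 1, 0.395 without Post-weaning replicate 1 and 0.064 without Post-weaning replicate 3. Iron handling genes lost it at adjusted p = 0.115 without Virgin replicate 1, 0.0600 without Post-weaning replicate 2 and 0.0604 without Post-weaning replicate 3. Matrix genes lost it at adjusted p = 0.113 without Virgin replicate 1 and 0.0691 without Virgin replicate 3, and type I interferon genes at 0.113 without Virgin replicate 1, 0.27 without Virgin replicate 3 and 0.116 without Post-weaning replicate 1.

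From pregnancy to lactation, 19 of the 31 inflammatory and NF-kB target genes rose, as did Cd36, while the cathepsin D gene and the growth factor genes Igf1 and Pdgfc fell. With an estimated correlation 0 of the 12 lists called by camera kept their call (inflammatory genes adjusted p = 0.131 with an estimated correlation). Cxcl3 rose from 15 ± 5.07 to 499 ± 43.7 CPM (log2 fold change 5.05 ± 0.49, adjusted p = 0.000295, n = 3 per stage). Il10 rose from 104 ± 30.8 to 971 ± 416 CPM (log2 fold change 3.23 ± 0.38, adjusted p = 0.000879). Nfkb1, which encodes the p50 subunit of NF-kB, rose from 33 ± 1.53 to 220.1 ± 67.9 CPM (log2 fold change 2.74 ± 0.34, adjusted p = 0.00107). Cd36 rose from 152 ± 124 to 2055 ± 331 CPM (log2 fold change 3.76 ± 0.51, adjusted p = 0.0022). Ctsd fell from 2868 ± 566 to 227 ± 44 CPM (log2 fold change -3.66 ± 0.41, adjusted p = 0.000717). Ctsd (Entrez gene 13033) lies on chromosome 7, 142375910 to 142387827. Igf1 had 0 counts in lactating and 11.2 ± 2.88 CPM in pregnant libraries, at least 93.2-fold lower in pooled counts (adjusted p = 0.000717). Pdgfc, a platelet-derived growth factor gene, fell from 21.7 ± 2.28 to 0.176 ± 0.304 CPM (log2 fold change -6.54 ± 0.92, adjusted p = 0.0026).

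Of the inflammatory and NF-kB target genes, 19 of the 31 tested members rose, and 24 did so adjusted over the list alone. Inflammatory and NF-kB target genes had a median log2 fold change of 2.0, camera adjusted p = 3.3e-19, and adjusted p = 0.131 with an estimated correlation. Of the immediate early and stress genes, 10 of the 31 tested members rose, and 15 did so adjusted over the list alone. Immediate early and stress genes had a median log2 fold change of 1.25, camera adjusted p = 7.79e-12, and adjusted p = 0.131 with an estimated correlation. They include the stress-induced gene Gadd45b (log2 fold change 2.39 ± 0.23, adjusted p = 0.000295) and Socs3, a suppressor of cytokine signalling (log2 fold change 1.82 ± 0.28, adjusted p = 0.00445). Of the iron handling genes, 4 of the 20 tested members rose (Slc11a1, Slc11a2, Fth1 and Hmox1) and 1 fell (Slc40a1), and 4 rose and 2 fell adjusted over the list alone. Iron handling genes had a median log2 fold change of 0.52, camera adjusted p = 0.0249, and adjusted p = 0.131 with an estimated correlation. Their mean log2 fold change was -0.08, opposite in sign to their median and their test. Slc11a2 (log2 fold change 2.88 ± 0.30, adjusted p = 0.000438) and Slc11a1 (log2 fold change 2.52 ± 0.32, adjusted p = 0.00146) encode divalent metal transporters. Of the glucocorticoid and steroid response genes, 4 of the 18 tested members rose (Il1r2, Errfi1, Mt2 and Mt1) and 1 fell (Pik3ip1), and 9 rose and 2 fell adjusted over the list alone. Glucocorticoid and steroid response genes had a median log2 fold change of 1.11, camera adjusted p = 0.000155, and adjusted p = 0.0617 with an estimated correlation. Mt1, a metallothionein gene, rose from 566 ± 73.3 to 1910.2 ± 436 CPM (log2 fold change 1.75 ± 0.21, adjusted p = 0.000892). Of the cholesterol biosynthesis genes, 5 of the 24 tested members rose (Srebf2, Fdps, Pmvk, Insig1 and Msmo1), and 7 did so adjusted over the list alone. Cholesterol biosynthesis genes had a median log2 fold change of 1.85, camera adjusted p = 0.000155, and adjusted p = 0.387 with an estimated correlation.

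Of the cell cycle genes, 1 of the 45 tested members rose (Cdt1) and 2 fell (Hmmr and Nusap1), and 1 rose and 3 fell adjusted over the list alone. Cell cycle genes had a median log2 fold change of -1.65, camera adjusted p = 6.88e-06, and adjusted p = 0.21 with an estimated correlation. Hmmr had 0 counts in lactating and 32.1 ± 2.69 CPM in pregnant libraries, at least 246-fold lower in pooled counts (adjusted p = 0.011). Of the oxidative phosphorylation genes, 2 of the 59 tested members fell (Atp5j and Atp5g3), and 6 did so adjusted over the list alone. Oxidative phosphorylation genes had a median log2 fold change of -0.41, camera adjusted p = 0.000247, and adjusted p = 0.21 with an estimated correlation. Of the lysosomal genes, 2 of the 45 tested members fell (Acp2 and Ctsd), and 2 did so adjusted over the list alone. Lysosomal genes had a median log2 fold change of -0.31, camera adjusted p = 0.0279, and adjusted p = 0.775 with an estimated correlation. Of the glycolysis and hypoxia genes, 1 of the 26 tested members rose (Pfkfb4), and 1 did so adjusted over the list alone. Glycolysis and hypoxia genes had a median log2 fold change of 0.34, camera adjusted p = 0.0284, and adjusted p = 0.131 with an estimated correlation. The perivascular macrophage list was not called (camera adjusted p = 0.745, direction up), and 3 of the 13 tested members rose (Mgl2, Pf4 and Fcgrt), and 3 rose and 1 fell adjusted over the list alone. Pf4, which encodes platelet factor 4 (log2 fold change 2.98 ± 0.35, adjusted p = 0.000853), and the lectin gene Mgl2 (log2 fold change 2.55 ± 0.50, adjusted p = 0.0149) were among them. Opposite in sign to its test, the list had a median log2 fold change of -1.30 (-0.28 with members absent from 1 stage at their bound) and a mean of -0.75. Its share of counts was 0.161 ± 0.0578% in lactating and 0.423 ± 0.133% in pregnant libraries (exact permutation p = 0.1), the smallest p possible.

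Of the endothelial genes, 0 of the 17 tested members passed the test, and 7 rose adjusted over the list alone. Endothelial genes had a median log2 fold change of 5.75 (5.57 with members absent from 1 stage at their bound), camera adjusted p = 0.000104, and adjusted p = 0.479 with an estimated correlation. They took 0.0812% of the counts in Lactating replicate 3, against 0.000493% and 0.00409% in the other lactating libraries. Of the basal and myoepithelial genes, 0 of the 16 tested members passed the test, with 0 adjusted over the list alone. Basal and myoepithelial genes had a median log2 fold change of 1.85, camera adjusted p = 0.00672, and adjusted p = 0.479 with an estimated correlation. Of the milk protein genes, 2 of the 19 tested members rose (Cidea and Csn1s2b), and 2 did so adjusted over the list alone. Milk protein genes had a median log2 fold change of 2.15, camera adjusted p = 0.0308, and adjusted p = 0.775 with an estimated correlation. Cidea lost its call without Lactating replicate 3, among other libraries (edgeR adjusted p = 0.288). Csn2 had 4974 ± 8158 CPM in lactation and 1294 ± 1575 CPM in pregnancy (edgeR adjusted p = 0.47).

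In edgeR's test 488 of the 12672 genes tested changed, 336 higher and 152 lower, with 2357 at an unadjusted p under 0.05. Over all genes tested, 3386 (26.7%) had no overlap between the 2 stages, where chance gives 10%, and 484 of them were among those called. With the 6 libraries of these stages alone the count was 147. It was 230, 194 and 291 without Pregnant replicate 1, 2 and 3. It was 274 higher and 239 lower without Lactating replicate 1 and 224 higher and 172 lower without Lactating replicate 2, and with DESeq2 1465, 773 higher and 692 lower. 29 of the 48 named genes that were called kept their call whichever replicate was left out, among them Cd36, Ctsd, Cxcl3, Gadd45b, Igf1, Il10, Mt1, Nfkb1, Pdgfc, Pf4, Slc11a1, Slc11a2 and Socs3. Lost calls numbered 14, 19 and 15 without Pregnant replicate 1, 2 and 3, and 7, 9 and 3 without Lactating replicate 1, 2 and 3. For genes given above that lost theirs, the highest edgeR adjusted p was 0.288 for Cidea without Lactating replicate 3. It was 0.164 for Pmvk, 0.121 for Fdps, 0.12 for Insig1, 0.109 for Csn1s2b, 0.0927 for Nusap1, 0.0818 for Mgl2, 0.0643 for Cdt1 and 0.0505 for Hmmr without Pregnant replicate 2. It was 0.155 for Fcgrt without Pregnant replicate 1. Endothelial, basal and lysosomal genes lost their list call at adjusted p = 0.0862, 0.0945 and 0.667 without Lactating replicate 3. Milk protein genes lost it at adjusted p = 0.122 without Pregnant replicate 2, 0.0872 without Pregnant replicate 3 and 0.787 without Lactating replicate 3. Glycolysis genes lost it at adjusted p = 0.0671 without Pregnant replicate 2, 0.0838 without Pregnant replicate 3 and 0.0676 without Lactating replicate 1, and iron handling genes at 0.0866 without Pregnant replicate 3.

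From lactation to 1 month after weaning, the chemokine genes Cxcl3 and Ccl9 and the mevalonate pathway gene Fdps fell, and Igf1 and Cx3cr1 rose. With an estimated correlation 0 of the 7 lists called by camera kept their call. Cxcl3 fell from 499 ± 43.7 to 46.7 ± 4.11 CPM (log2 fold change -3.42 ± 0.45, adjusted p = 0.00572, n = 3 per stage). Ccl9, a macrophage chemokine gene, fell from 636 ± 247 to 79.5 ± 26.1 CPM (log2 fold change -3.0 ± 0.35, adjusted p = 0.00534). Fdps fell from 56.9 ± 11.2 to 4.57 ± 0.992 CPM (log2 fold change -3.63 ± 0.48, adjusted p = 0.00572). Oasl1, an antiviral gene, fell from 261 ± 109 to 23.5 ± 10.2 CPM (log2 fold change -3.47 ± 0.46, adjusted p = 0.00572). Igf1 had 0 counts in lactating and 45.7 ± 16.5 CPM in post-weaning libraries, at least 339-fold higher in pooled counts (adjusted p = 0.00294). Cx3cr1 rose from 206 ± 23.3 to 419.8 ± 61.3 CPM (log2 fold change 1.03 ± 0.20, adjusted p = 0.0396). Cx3cr1 (Entrez gene 13051) lies on chromosome 9, 120048683 to 120068296. Krt19 had 0 counts in lactating and 85 ± 57.8 CPM in post-weaning libraries, at least 636-fold higher in pooled counts (adjusted p = 0.00754).

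Of the inflammatory and NF-kB target genes, 4 of the 31 tested members fell (Ccl5, Ccl4, Nfkb1 and Cxcl3), and 14 did so adjusted over the list alone. Inflammatory and NF-kB target genes had a median log2 fold change of -0.91, camera adjusted p = 3.76e-07, and adjusted p = 0.566 with an estimated correlation. Of the cholesterol biosynthesis genes, 2 of the 24 tested members fell (Srebf2 and Fdps), and 10 did so adjusted over the list alone. Cholesterol biosynthesis genes had a median log2 fold change of -1.92, camera adjusted p = 7.18e-07, and adjusted p = 0.566 with an estimated correlation. Of the homeostatic microglia genes, 1 of the 14 tested members rose (Cx3cr1), and 5 did so adjusted over the list alone. Homeostatic microglia genes had a median log2 fold change of 0.40, camera adjusted p = 0.012, and adjusted p = 0.566 with an estimated correlation. Of the ribosomal protein genes, 1 of the 78 tested members fell (Rpl8), and 1 did so adjusted over the list alone. Ribosomal protein genes had a median log2 fold change of -0.56, camera adjusted p = 1.84e-10, and adjusted p = 0.566 with an estimated correlation. Of the milk protein genes, 1 of the 19 tested members fell (Csn1s2b), and 9 did so adjusted over the list alone. Milk protein genes had a median log2 fold change of -3.81, camera adjusted p = 0.000112, and adjusted p = 0.566 with an estimated correlation. Their share of counts was 2.62 ± 4.23% in lactation and 0.117 ± 0.0863% after weaning. Of the luminal epithelial genes, 1 of the 24 tested members rose (Krt19), and 7 did so adjusted over the list alone. Luminal epithelial genes had a median log2 fold change of 2.66, camera adjusted p = 2.4e-06, and adjusted p = 0.566 with an estimated correlation. Of the fibroblast genes, 0 of the 15 tested members passed the test, and 7 rose adjusted over the list alone. Fibroblast genes had a median log2 fold change of 6.99 (4.75 with members absent from 1 stage at their bound), camera adjusted p = 0.0033, and adjusted p = 0.566 with an estimated correlation. Their share of counts was 0.0618 ± 0.0162% in post-weaning and 0.0375 ± 0.00775% in lactating libraries (exact permutation p = 0.1).

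In edgeR's test 117 of the 12672 genes tested changed, 58 higher and 59 lower, with 1912 at an unadjusted p under 0.05. Over all genes tested, 2735 (21.6%) had no overlap between the 2 stages, where chance gives 10%, and 117 of them were among those called. With the 6 libraries alone the count was 3, and with DESeq2 on all 12 it was 919, 588 higher and 331 lower. It was 242 without Lactating replicate 3. It was 128 higher and 50 lower without Lactating replicate 1 and 80 higher and 31 lower without Lactating replicate 2. It was 32 higher and 12 lower without Post-weaning replicate 1, 17 higher and 9 lower without Post-weaning replicate 2 and 21 higher and 10 lower without Post-weaning replicate 3. 11 of the 19 named genes that were called kept their call whichever replicate was left out, among them Ccl9, Cxcl3, Fdps, Igf1, Krt19 and Oasl1. Lost calls numbered 3 and 4 without Lactating replicate 1 and 2, and 7, 8 and 8 without Post-weaning replicate 1, 2 and 3. For genes given above that lost theirs, the highest edgeR adjusted p was 0.196 for Ccl5, 0.173 for Nfkb1 and 0.165 for Csn1s2b without Post-weaning replicate 2. It was 0.165 for Cx3cr1 without Post-weaning replicate 3. The count of lists called was 13 without Lactating replicate 1 and 14 without Lactating replicate 3. Homeostatic microglia genes lost their call at adjusted p = 0.318 without Lactating replicate 3 and 0.0558 without Post-weaning replicate 3. Without Lactating replicate 3, endothelial, macrophage identity and unfolded protein response genes turned direction and were called at adjusted p = 0.028, 0.00869 and 0.0231.

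From pregnancy to 1 month after weaning, 3 of the 25 apoptotic cell uptake and 9 of the 31 immediate early and dissociation stress genes rose. Both lists kept their call with an estimated correlation. The fall from virgin used the same pregnant libraries, so the reversal is not independent. Trem2 rose from 3.52 ± 2.66 to 61.7 ± 8.21 CPM (log2 fold change 4.15 ± 0.65, adjusted p = 0.0184, n = 3 per stage). Lrp1 rose from 6.12 ± 0.598 to 65.2 ± 18.1 CPM (log2 fold change 3.41 ± 0.52, adjusted p = 0.0165). Cd36 rose from 152 ± 124 to 1178 ± 255 CPM (log2 fold change 2.96 ± 0.50, adjusted p = 0.0231). Fcgrt, which encodes the neonatal Fc receptor, rose from 32.3 ± 5.26 to 228 ± 56 CPM (log2 fold change 2.82 ± 0.35, adjusted p = 0.00796). Ifi30, a lysosomal thiol reductase gene of antigen processing, fell from 701 ± 55.1 to 187 ± 50.3 CPM (log2 fold change -1.91 ± 0.22, adjusted p = 0.0062). Cfp, the properdin gene of the complement system, fell from 602 ± 116 to 46.9 ± 21.6 CPM (log2 fold change -3.68 ± 0.61, adjusted p = 0.0231). H2-Q7, an MHC class Ib gene whose close paralogs make its counts uncertain, fell from 124 ± 11 to 27.7 ± 4.03 CPM (log2 fold change -2.16 ± 0.33, adjusted p = 0.0165).

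Of the immediate early and stress genes, 9 of the 31 tested members rose, and 19 did so adjusted over the list alone. Immediate early and stress genes had a median log2 fold change of 1.53, camera adjusted p = 3.98e-22, and adjusted p = 0.0218 with an estimated correlation. Fos rose from 532 ± 87.3 to 1777 ± 315 CPM (log2 fold change 1.74 ± 0.22, adjusted p = 0.00796). Of the apoptotic cell uptake genes, 3 of the 25 tested members rose (Lrp1, Trem2 and Cd36), and 4 did so adjusted over the list alone. Apoptotic cell uptake genes had a median log2 fold change of 0.38, camera adjusted p = 0.000244, and adjusted p = 0.0381 with an estimated correlation. Of the cell cycle genes, 0 of the 45 tested members passed the test, with 0 adjusted over the list alone. Cell cycle genes had a median log2 fold change of -1.93, camera adjusted p = 1.59e-15, and adjusted p = 0.0218 with an estimated correlation. Of the oxidative phosphorylation genes, 1 of the 59 tested members fell (Atp5g3), and 13 did so adjusted over the list alone. Oxidative phosphorylation genes had a median log2 fold change of -0.53, camera adjusted p = 2.04e-12, and adjusted p = 0.0218 with an estimated correlation. Of the iron handling genes, 1 of the 20 tested members rose (Slc11a1), and 2 did so adjusted over the list alone. Iron handling genes had a median log2 fold change of 0.39, camera adjusted p = 0.000411, and adjusted p = 0.0218 with an estimated correlation. Of the glucocorticoid and steroid response genes, 1 of the 18 tested members rose (Errfi1), and 3 did so adjusted over the list alone. Glucocorticoid and steroid response genes had a median log2 fold change of 0.85, camera adjusted p = 0.000411, and adjusted p = 0.0218 with an estimated correlation. Of the inflammatory and NF-kB target genes, 4 of the 31 tested members rose (Il10, Nfkbia, Cxcl1 and Birc3), and 12 did so adjusted over the list alone. Inflammatory and NF-kB target genes had a median log2 fold change of 1.03, camera adjusted p = 2.85e-11, and adjusted p = 0.184 with an estimated correlation.

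Of the matrix remodelling and growth factor genes, 2 of the 31 tested members rose (Osm and Adam8), and 7 rose and 2 fell adjusted over the list alone. Matrix remodelling and growth factor genes had a median log2 fold change of 1.06, camera adjusted p = 0.000618, and adjusted p = 0.0989 with an estimated correlation. Of the perivascular and stromal resident macrophage genes, 1 of the 13 tested members rose (Fcgrt), and 5 did so adjusted over the list alone. Perivascular and stromal resident macrophage genes had a median log2 fold change of 0.81, camera adjusted p = 0.00191, and adjusted p = 0.216 with an estimated correlation. Of the MHC class I genes, 1 of the 19 tested members fell (H2-Q7), and 1 did so adjusted over the list alone. MHC class I genes had a median log2 fold change of -0.39, camera adjusted p = 0.000618, and adjusted p = 0.191 with an estimated correlation. Of the ribosomal protein genes, 0 of the 78 tested members passed the test, with 0 adjusted over the list alone. Ribosomal protein genes had a median log2 fold change of -0.65, camera adjusted p = 3.32e-10, and adjusted p = 0.337 with an estimated correlation. Of the endothelial genes, 0 of the 17 tested members passed the test, with 0 adjusted over the list alone. Endothelial genes had a median log2 fold change of 4.39 (4.26 with members absent from 1 stage at their bound), camera adjusted p = 1.26e-05, and adjusted p = 0.337 with an estimated correlation. Their share of counts was 0.00119 ± 0.000821% in pregnancy and 0.00949 ± 0.00681% after weaning. Of the fibroblast genes, 0 of the 15 tested members passed the test, with 0 adjusted over the list alone. Fibroblast genes had a median log2 fold change of 3.87 (3.65 with members absent from 1 stage at their bound), camera adjusted p = 0.000281, and adjusted p = 0.191 with an estimated correlation. The fibroblast share of counts was 0.0618 ± 0.0162% in post-weaning and 0.0616 ± 0.00527% in pregnant libraries (exact permutation p = 1). Of the luminal epithelial genes, 0 of the 24 tested members passed the test, with 0 adjusted over the list alone. Luminal epithelial genes had a median log2 fold change of 2.16, camera adjusted p = 3.58e-06, and adjusted p = 0.337 with an estimated correlation.

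In edgeR's test 91 of the 12672 genes tested changed, 73 higher and 18 lower, with 1297 at an unadjusted p under 0.05. Over all genes tested, 3508 (27.7%) had no overlap between the 2 stages, where chance gives 10%, and 91 of them were among those called. The count was 33, 1 and 6 without Pregnant replicate 1, 2 and 3. It was 15, 10 and 9 without Post-weaning replicate 1, 2 and 3. Without Lactating replicate 3, a fit chosen after seeing the data, it was 308, and with edgeR on the 6 libraries alone 590. None of the 22 named genes that were called kept its call whichever replicate was left out. Lost calls numbered 14, 22 and 19 without Pregnant replicate 1, 2 and 3, and 16, 18 and 18 without Post-weaning replicate 1, 2 and 3. For genes given above that lost theirs, the highest edgeR adjusted p was 0.211 for Cxcl1, 0.211 for Il10, 0.194 for Birc3, 0.132 for Trem2, 0.131 for Cd36, 0.124 for H2-Q7, 0.124 for Lrp1, 0.0676 for Fos, 0.0674 for Fcgrt and 0.0579 for Ifi30 without Pregnant replicate 2. It was 0.136 for Cfp without Post-weaning replicate 3.

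**Figure D3:**
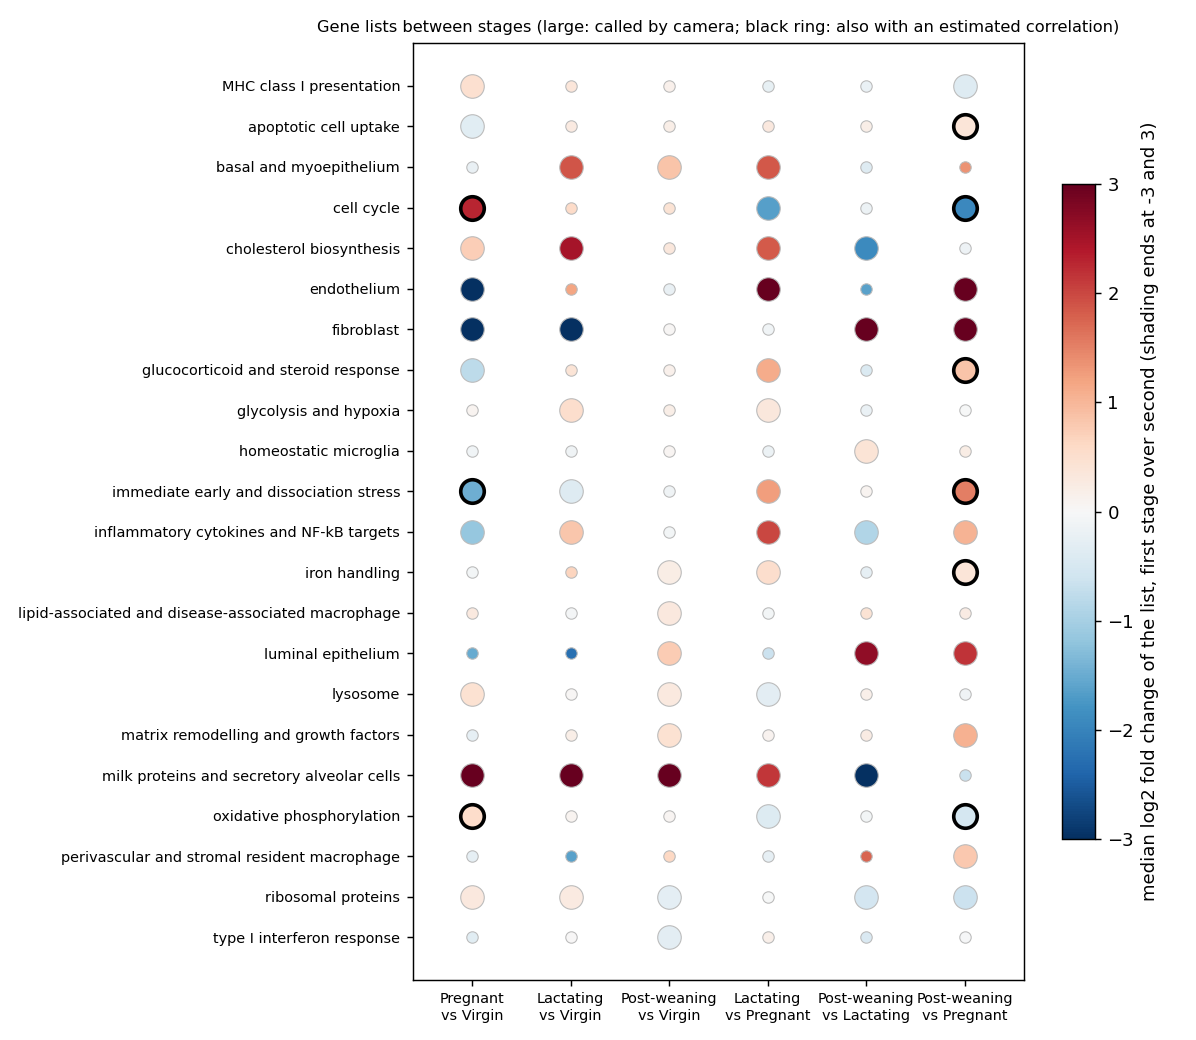
Median log2 fold change of gene lists (colour, shading ends at -3 and 3, members absent from 1 stage set at their bound) by list (y axis) and comparison (x axis). Large circles passed camera at an adjusted p of 0.05, and black rings mark the 3 lists in pregnancy against virgin and the 6 after weaning against pregnancy that also passed with an estimated correlation.

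**Figure D4:**
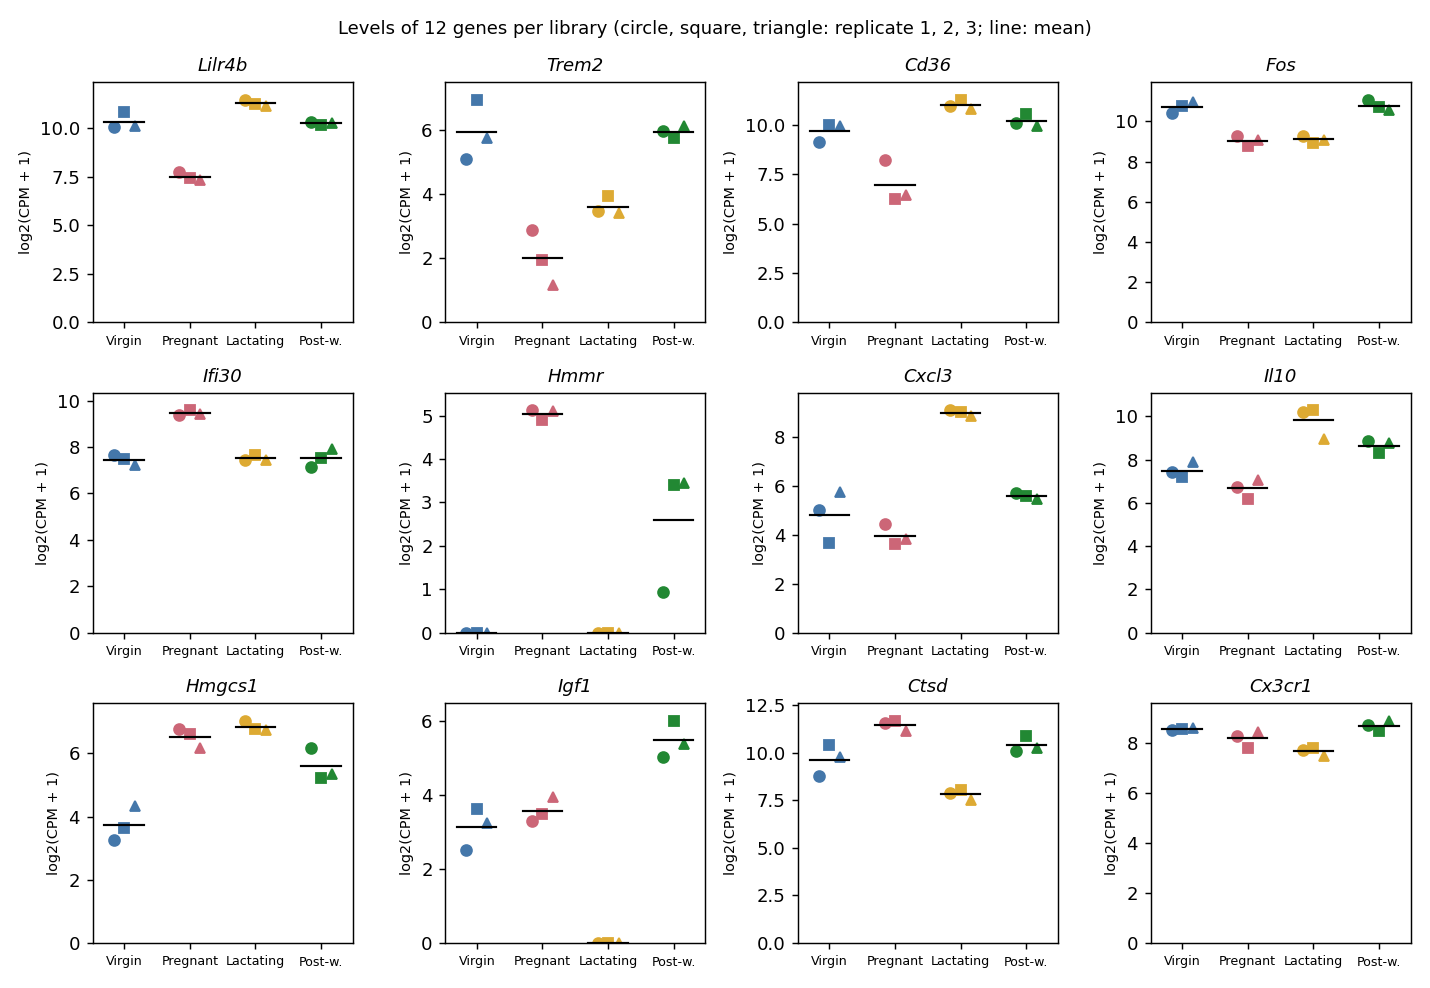
Levels of 12 genes as log2(CPM + 1) (y axis) in each library of the 4 stages (x axis), with a circle, square and triangle for replicates 1, 2 and 3 and a line for the mean. Lilr4b averages 180.1 ± 25.9 CPM in pregnancy and 1319 ± 417 CPM in virgin libraries, Cxcl3 499 ± 43.7 CPM in lactation, and Igf1 has 0 counts in the 3 lactating libraries (SD, n = 3).

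Across all stages, 424 of the 12672 genes differed in edgeR's test of any difference between the 4 stages, with 2113 at an unadjusted p under 0.05. The count was 188, 171 and 205 without Pregnant replicate 1, 2 and 3. It was 265 and 773 without Lactating replicate 2 and 3, and 235 and 256 without Post-weaning replicate 2 and 3. Fold changes were also compared between pairs of comparisons that share no library. Across 12672 genes, which are not independent replicates, the fold change of pregnancy over virgin correlated with that of lactation over post-weaning at Pearson's r = 0.0625 and Spearman's rho = 0.0408. Of the 167 and 117 genes called, 3 were higher in both (Zmynd15, Slc38a1 and Fabp3, 0.261 if calls were independent). Another 3 were lower in both (Fos, Gng12 and Hpgd, 0.508) and 7 moved in opposite directions (0.773). Without Virgin replicate 3 the correlation turned to -0.0733, and without Pregnant replicate 1 it was 0.111. The fold change of lactation over virgin correlated with that of pregnancy over post-weaning at r = 0.129 and rho = 0.0526, and at r = 0.0275 without Virgin replicate 3. Here 4 genes were higher in both (Fastkd3, Slc38a1, Glycam1 and Fabp3, chance 0.188), 5 lower in both (Igfbp5, Fos, Egr1, Slco2b1 and Hpgd, chance 0.657) and 11 moved in opposite directions (chance 0.922). That a gene changed in 1 comparison and not in another was not tested as a difference between comparisons.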

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

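The fits without Lactating replicate 3 in the comparisons that do not include lactation were chosen after the results were seen, and the other alternatives before. Counts of changed genes stayed within 1.5 times under RLE size factors, TMM without milk, epithelial, ribosomal and mitochondrial genes, no filter and the strict filter, in all comparisons. The order is pregnant, lactating and post-weaning against virgin, lactating against pregnant, and post-weaning against lactating and pregnant. DESeq2 called 656, 1173, 125, 1465, 919 and 502 genes, with 1462 for any stage. The 44.9% false calls simulated for pregnant against virgin set no rate for these. limma-voom called 298 in pregnant against virgin, 11, 201 and 167 in post-weaning against virgin, lactating and pregnant, and 724 for any stage, with the others within that bound. With quality weights it called 473, 1, 998, 387 and 899 in that order without lactating against virgin, and 867 for any stage. In lactating against virgin it called 246, 181 higher and 65 lower, 149 of which edgeR also called, and in post-weaning against lactating 140 higher and 247 lower. The test against a 2-fold change called 1, 41, 129, 24 and 1 in that order without post-weaning against virgin, where the count was 0, and was not run for any stage. Fits to the 6 libraries compared called 0, 1, 147, 3 and 590 in that order without pregnant against virgin, whose count stayed within the bound. Leaving out 1 library gave 40 to 438, 111 to 416, 0 to 10, 194 to 689, 26 to 242 and 1 to 308 genes, and 171 to 773 for any stage. The highest counts came without Lactating replicate 3 in all of these, and the lowest without Pregnant replicate 2 in pregnant against virgin, Virgin replicate 1 in lactating against virgin, Pregnant replicate 2 in lactating against pregnant, Post-weaning replicate 2 in post-weaning against lactating and Pregnant replicate 2 in post-weaning against pregnant. That replicate is also in the fit of the comparisons without lactation, where all 167 genes of pregnant against virgin and all 91 of post-weaning against pregnant were called again without it. Fits with fewer libraries have fewer samples, and for the other differences the cause was not tested.

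The replicate numbers were checked as a block. Same-numbered libraries of different stages did not deviate together, with a mean correlation of 0.00328 over 18 pairs (-0.0683 to 0.0726, 0 over 0.1), so the numbers do not pair the samples. With the block the counts were 100, 139, 0, 346, 42 and 35 genes and 223 for any stage, and 13, 10, 7, 12, 9 and 17 lists.

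TMM without milk, epithelial, ribosomal and mitochondrial genes called 13 lists in lactating against virgin. Leaving out 1 library gave 11 to 15, 8 to 11, 5 to 12, 10 to 16, 7 to 14 and 14 to 17 lists. Direction turned for ribosomal proteins in pregnant against virgin without Pregnant replicate 3 (adjusted p = 0.204, and 6.54e-05 without Pregnant replicate 1). It turned for endothelium in lactating against virgin without Lactating replicate 3 (adjusted p = 0.0215, and 0.0121 without Lactating replicate 1 and 0.719 without Virgin replicate 1). In post-weaning against lactating it turned without that replicate for endothelium (adjusted p = 0.028, and 0.0044 without Lactating replicate 1 and 0.952 without Post-weaning replicate 2), macrophage identity (adjusted p = 0.00869, and 0.93 without Post-weaning replicate 3) and the unfolded protein response (adjusted p = 0.0231, and 0.893 without Post-weaning replicate 2). In all, 2137 of 2358 list results kept their side of the threshold, 106 lost and 110 gained a call, and 5 turned direction. Of 3168 results for named genes, 2537 kept their side, 601 lost and 30 gained a call, and 0 turned direction. Direction was compared only where the main or the alternative fit made a call. A further 17 gave no value, because the strict filter removed the gene or DESeq2 gave it no adjusted p. Of 151 calls of named genes, 62 were kept whichever replicate was left out. Of 716 shares, 23 moved by more than 1 SD. The correlation of pregnancy over virgin with lactation over post-weaning ran from -0.0733, without Virgin replicate 3, to 0.111. That of lactation over virgin with pregnancy over post-weaning ran from 0.0275 to 0.18, with 0.0886 without the filter, 0.0526 as Spearman's rho and 0.117 with the block. Depth limits the folds of genes absent from a stage to lower bounds. The spread between libraries (coefficient of variation 0.856) limits which 2-fold changes can be called.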

Other observations

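The fit without Lactating replicate 3 and the tests on library quality, immediate early genes, milk transcripts and other splits of the samples were chosen after the results they bear on were seen. In that fit, edgeR called 10 genes between post-weaning and virgin libraries that it did not call with all 12, all of them higher after weaning, with n = 3 per stage. H2-M2, a nonclassical MHC class I gene, rose most firmly (log2 fold change 1.67 ± 0.13, adjusted p = 0.000375), with 1004 ± 56.4 CPM in virgin, 1000.1 ± 92.2 in pregnant, 5052 ± 2972 in lactating and 3160.5 ± 333 in post-weaning libraries. Adamdec1, a metalloprotease gene of tissue macrophages, rose too (log2 fold change 3.73 ± 0.35, adjusted p = 0.00187), with 71.5 ± 32.1 CPM in virgin, 1194 ± 165 in pregnant, 364 ± 264 in lactating and 940.0 ± 243 in post-weaning libraries. Bhlhe40, a transcription factor gene (log2 fold change 1.5 ± 0.20, adjusted p = 0.0223), had 66.7 ± 12.6 CPM in virgin, 237 ± 20.7 in pregnant, 319.9 ± 61.4 in lactating and 187 ± 20.3 in post-weaning libraries. Acp5, which encodes tartrate-resistant acid phosphatase (log2 fold change 0.87 ± 0.12, adjusted p = 0.0223), had 737 ± 77.9 CPM in virgin, 1969 ± 53.3 in pregnant, 2750.2 ± 1050.4 in lactating and 1329 ± 29.4 in post-weaning libraries. The sterol synthesis gene Cyp51 (log2 fold change 1.94 ± 0.28, adjusted p = 0.0262) and the zinc finger gene Zmynd15 (log2 fold change 1.16 ± 0.16, adjusted p = 0.0223) were called as well. The scavenger receptor gene Colec12, 1700071M16Rik and the casein gene Csn1s1 had 0 counts in virgin libraries and 13.2 ± 3.71, 6.79 ± 4.22 and 191 ± 122 CPM after weaning (adjusted p = 0.0223, 0.0223 and 0.0223), and Csn2 was the last of the 10 (adjusted p = 0.0262). With all 12 libraries their adjusted p ran from 0.10 to 0.763. Comparisons sharing a stage share the chance values of its libraries.

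Lactating replicate 3 stands apart from the other lactating libraries. Lower sequencing depth is argued against, since its total was 1.43 times the highest of theirs. Dilution by RNA of other cells, at a macrophage identity share 0.417 times the mean of the other lactating libraries, is argued against as the whole cause. 80 of 4466 genes at 20 CPM or more in both other lactating libraries (1.79%) had 0 counts in it, where dilution alone would leave at least 71.3 counts of each, and the highest such number in another library was 14. A candidate explanation that stays open is that fewer RNA molecules were captured, as 10018 genes were detected after thinning every library to the smallest total, against 11110 in the next lowest, and no biological explanation was tested.

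The immediate early genes were lower in the pregnant than in the virgin libraries. A scaling factor moves all genes of a library alike, and is argued against as the cause, since the list median minus the median of all genes tested was -1.50, with camera adjusted p = 0.0348 with an estimated correlation. Milder cell isolation for the pregnant samples, which may lower the same genes, remains open. The 6 heat-shock chaperones of the list, which respond to handling too, had a median log2 fold change of -0.77 (-1.52 to 0.17, 0 called), between the bounds set for and against it, while the other 25 members had a median of -1.74 with 24 lower. The stage itself stays open as a biological explanation and was not tested apart from the isolation.

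Milk transcripts were counted in the post-weaning libraries, with 23619 counts of Csn3 and 6057 of Csn1s1 over the 3 libraries. Reads carried over from the lactating libraries are argued against, since Csn1s2b and Wap, abundant in lactation, had 0 counts together where the ratio to Csn2 in the lactating libraries gives 1588. RNA of mammary epithelial cells in the sorted samples, in which the luminal keratin gene Krt19 stood at 85 ± 57.8 CPM, is a candidate source. The ratio of milk to luminal epithelial counts varied 1.6-fold between the 3 libraries, less than the milk share (4.22-fold) and the luminal share (3.13-fold). Milk transcripts within the macrophages themselves were not tested for, and the gate that would remove epithelial cells is not given in the sources used here.

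The samples were also split in other ways. For the comparisons of 3 libraries with 3, 10 splits exist, too few for a share under 0.05. In the order used in the account of the alternatives, the real split gave 167, 246, 0, 488, 117 and 91 genes and the highest of the other splits 0, 2, 0, 0, 0 and 0, and 1, 1, 10, 1, 1 and 1 of the 10 splits reached the real count. For lists, the real split gave 13, 8, 9, 12, 7 and 14 and the highest other 8, 13, 7, 15, 16 and 16, with 1, 4, 1, 4, 5 and 3 of the 10 splits reaching the real count. For any difference between the 4 stages, 1 of 100 splits, the real one, gave as many as 424 genes, and the highest other gave 51. Chance is argued against there, though 1 of 100 is the smallest share that these splits can give. For the correlations of fold changes, 57 and 23 of 100 splits reached the real 0.0625 and 0.129, with 0.272 and 0.277 as the highest others, so chance cannot be excluded for either.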
